A study of Mus musculus with 6 samples.

How the data were processed

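The series holds 6 RNA-seq libraries of endothelial cells from the cerebellum of mice at postnatal day 9, 3 labelled wild-type and 3 labelled Ccm3 knock-out. The sample titles do not say how many mice a library holds. Ccm3 is an older name of Pdcd10, a gene in which loss-of-function mutations cause cerebral cavernous malformations, clusters of enlarged and leaky brain vessels. Per the labels' protocols, cerebella were dissociated with a kit for adult brain, CD45 beads and CD31 beads were used to isolate the endothelial cells, and total RNA was made into stranded libraries after depletion of ribosomal RNA. CD45 marks leukocytes and CD31 (Pecam1) marks endothelial cells, platelets and some leukocytes. Groups and replicate numbers were taken from the sample titles.

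Per the submitters' processing notes, reads were handled with Trim Galore and STAR version 2.5.3a against the GRCm38 build, and DESeq2 was used. The read counter, the gene annotation, any gene filter and the strand setting of the counting are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart with certainty. The deposited table holds a normalised signal per gene and library, gene counts that the authors divided by 1 size factor per library. Within a library 100% of the values were whole multiples of a single step, within a tolerance of 0.01 of a read, and the whole reads behind them were recovered. The table lists 14437 genes by Ensembl identifier, 14300 of them with a symbol. Another 81 were given a symbol from a reference table of names, and 14381 were found in GENCODE release M21 (GRCm38), which supplied the positions. The fewest reads of a listed gene over all 6 libraries was 12, so genes below some minimum are not analysed here. No column of sample values was left unused.

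The recovered reads per library ranged from 11075769 (knock-out 3) to 21142333 (wild-type 2), and a gene with 3 reads has a value between 1.96 and 3.41 depending on the library. With 3 libraries per group, the spread between replicate libraries limits the precision more than the depth does for genes at the median of 182 to 309 reads. Replicates were compared before they were averaged. The chi-square of recovered reads between replicates lay between 13.9 and 57.5 per degree of freedom, far above sampling noise, so no library was counted as a copy of another.

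Genes with a value of at least 10 in at least 3 libraries were kept (14076 genes). Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3 (linear model on genotype, empirical Bayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all genes kept and a limit of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and their 95% intervals come from the same model. A gene is said to have risen, fallen or changed only when it passed this test. Means are given with the SD over 3 libraries.

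Before the data were examined, 38 gene lists were written down, covering cavernous malformation biology, endothelial subtypes, barrier function, signalling pathways, stress and RNA quality, and markers of other cells that a CD31 isolate of cerebellum could hold. Of these, 37 had at least 3 members among the genes kept. The result of 1 of them and some single genes are not reported here. Too small was the list of other leukocytes, of which 2 of 24 genes were kept (Cd79a and Lcn2, neither of them changed). Some lists share genes. The barrier and capillary lists share 8, the lists of KLF targets and of matrix proteases share 5, and the activation and venous lists share 5. Each list was tested with camera, which asks whether its genes were shifted up or down relative to other genes. Rises and falls within a list can cancel in this test. It was run with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 37 lists. The count of members that changed is given over all genes tested and also adjusted over the list alone. Camera with a correlation estimated from the data and fry were run as alternatives. Fry asks whether a list's genes move, on balance, in the same direction, and does not compare the list with other genes. Every one of the 21 lists called with the preset correlation lost its call with the estimated correlation, and fry called 4 lists, the capillary, endothelial activation, Wnt and coagulation lists.

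The genes tested one by one in the text follow a rule fixed before the data were examined. It takes Pdcd10 and any changed member of the CCM list, the 12 largest rises and 12 largest falls among changed genes with a mean above the median and no overlap between the groups (predicted genes left out), and up to 4 members of each list with the smallest p. Klf2, Klf4, Klf6, Klf9, Klf10, Anxa1, Anxa2, Anxa3, Anxa5, Anxa7, Vegfa, Slc2a1, Cldn5, S100a6, Slc16a3, Slc39a8, Slc16a9, Tubb1, Itga2b, Gp1bb and Xist were added after their values were seen.

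The labels give both groups the numbers 1 to 3. The labels do not say what an equal number stands for. Deviations from the group means correlated at 0.101, 0.110 and 0.192 between libraries of equal number, each above 0.1, so the numbers were treated as a possible pairing and a fit with the replicate number as a block was compared with the fit without it. The pairing rests on the data alone, and wild-type 1 correlated more with knock-out 2 (0.295) than with knock-out 1. The block ended the calls of 193 genes and added 83, and it is given beside each named gene or list whose call it changed.

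Alternatives were other pseudocounts (0.5 and 8), no filter and a minimum of 50, TMM, upper-quartile and quantile scaling, robust and array-weighted limma, the replicate block, a minimum of 2-fold, and each library left out in turn. The edgeR 4.0.16 quasi-likelihood test and DESeq2 1.42.0 were run on the recovered reads. The edgeR test called 897 genes, against 879 with limma. Fits with the level of 4 Y-linked genes or the level of pericyte markers as a covariate were added after the data were seen. Each level was the mean log2(value + 1) of those genes. In such a fit the genotype changes of the genes that make up the level average 0 by construction, so it does not test them. In data simulated for this comparison with 14027 genes, limma recovered 58.6% of 99 genes changed 2-fold and 85.6% of 97 genes changed 4-fold, with 10 false calls among 151. It made 0 calls in a simulation without changes, where edgeR made 0 and DESeq2 16. Camera called 10 of 10 simulated lists shifted by 0.5 (log2) and 0 of 100 unshifted lists. The simulated genes varied independently and the lists were drawn at random. The simulation therefore cannot show how often camera calls real lists, whose genes can vary together, without a shift.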

Results

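Cerebellar endothelial cells, isolated with CD31 beads at postnatal day 9, were compared by RNA-seq between wild-type mice and mice labelled as knock-outs of Ccm3 (n = 3 libraries each). The aim was to find which genes change with the knock-out of this gene, also named Pdcd10. The libraries held 18225655, 21142333 and 16281778 recovered gene reads in wild-type 1, 2 and 3, and 15348546, 20566507 and 11075769 in knock-out 1, 2 and 3. Values are reads normalised by the authors' size factors, and fold changes are knock-out over wild-type from limma on log2(value + 1).

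Pdcd10, the targeted gene (ENSMUSG00000027835, chromosome 3, 75516490 to 75556856 of GRCm38, minus strand), had 529, 522 and 689 normalised reads in wild-type 1, 2 and 3. It had 230, 154 and 309 in knock-out 1, 2 and 3, so that all 3 knock-out libraries lay below all 3 wild-type libraries. The means were 580 ± 94.3 and 231 ± 77.4 (SD, n = 3), and the knock-out held 38.7% of the wild-type level (fold 0.39, 95% interval 0.26 to 0.57, adjusted p = 0.0162). The part of the gene that was deleted is not given in the sources used here, and reads over the whole gene need not fall to 0. Pdcd10 was the single gene that fell among 10 tested members of the CCM complex and its binding partners, none rose, and 9 were not called. Adjusted over the list alone, 1 rose and 1 fell. The small GTPases Rap1b and Rap1a, which act upstream of the adaptor Krit1, had folds of 1.31 (adjusted p = 0.061) and 1.20 (adjusted p = 0.211). The list was not called (median log2 change 0.23, adjusted p = 0.0553). None of 15 tested germinal centre kinases and STRIPAK components, the protein partners of Pdcd10, changed over all genes or adjusted over the list alone (list adjusted p = 0.346). Fgfr1op2 and Slmap, 2 of its scaffold members, had folds of 1.16 and 1.13. The call of Pdcd10 was lost without wild-type 1, 2 or 3 (adjusted p = 0.0513, 0.0602 and 0.0621), with log2 changes of -1.43, -1.44 and -1.24. Rap1b was called without knock-out 3 (0.0246), with quantile scaling (0.0382), with array weights (0.0213) and with DESeq2 (0.00555), and the CCM list was called without wild-type 3 (0.0344) or knock-out 3 (0.0187), with quantile scaling (0.0336) and with array weights (0.0339).

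In the knock-out, 507 genes rose and 372 fell among 14076 tested. The median fold of the risen genes was 1.92, and the fallen genes were a median of 1.74 times lower. The largest rise by the naming rule was that of Sele (chromosome 1, 164048234 to 164057677), which encodes E-selectin, a leukocyte adhesion molecule of activated endothelium. Sele went from 26.7 ± 4.11 to 705 ± 191 normalised reads, a 25.1-fold rise (17.4 to 36.2, adjusted p = 0.000425). Pgf, a ligand of the VEGF receptor Flt1, rose from 68.0 ± 16.0 to 902 ± 502 (95% interval of the fold 6.56 to 22.0), and S100a10, the partner of annexin A2 in plasminogen binding, rose 9.88-fold (5.23 to 18.7). Emp1 (7.78-fold), Inhbb (6.82), Dnah10 (6.56), Ndrg1 (6.47), Irx3 (6.43), the complement regulator Cd55 (6.19), Ly6a (5.84), Dync1i1 (5.09) and Cdh13 (4.73) completed the 12 largest rises. The largest fall was that of Lrrn3, a neuronal leucine-rich repeat protein, from 1244 ± 228 to 220 ± 114 (fold 0.16, 0.09 to 0.28, adjusted p = 0.00472). The abundant proteoglycan gene Spock2 fell from 98052 ± 8259 to 29156 ± 9272 (fold 0.29), the amino acid transporter Slc7a8 had a fold of 0.27 and the NAD salvage enzyme Nampt a fold of 0.34. Synpo2 (0.25), Ndnf (0.30), Syt15 (0.31), Htra1 (0.31), Ddc (0.32), Kank4 (0.33), Frem1 (0.34) and Hey1 (0.34) completed the 12 largest falls. All 12 rises and 9 of the 12 falls were called in each of the 6 fits that left out 1 library. The exceptions were Htra1 (adjusted p = 0.0536 without wild-type 2), Syt15 (0.0798 and 0.0515 without wild-type 2 and 3) and Kank4 (0.0691, 0.0978, 0.0804 and 0.0514 without wild-type 1, 2 and 3 and knock-out 2).

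**Figure D1:**
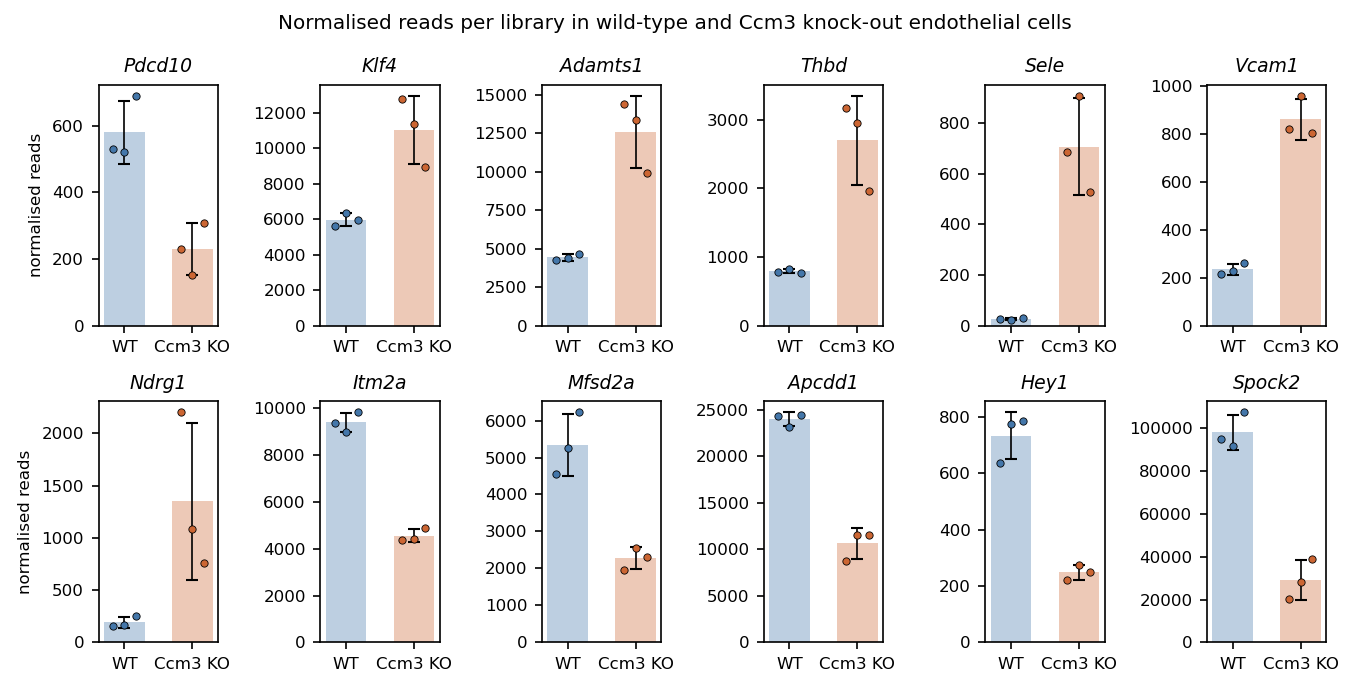
Normalised reads (linear axes from 0) of 12 genes in wild-type (WT, blue) and Ccm3 knock-out (KO, orange) libraries. Points are single libraries in the order of their numbers, bars are means and error bars are SDs over 3 libraries; in every panel the groups do not overlap, as for Pdcd10 with means of 580 and 231.

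At least 2-fold changes were found for 235 genes that rose and 124 that fell, 359 in all, against 205 without wild-type 2 and 234 without knock-out 2. The groups did not overlap for 3595 genes (25.5%, where chance gives 10%), and all 879 changed genes were among them. The count of changed genes fell to 399, 283, 439 and 459 without wild-type 1, 2 and 3 and knock-out 2. It was 1373 with DESeq2 on the recovered reads and 457 with the level of Y-linked genes in the fit.

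Genes of endothelial activation, cytokines and chemokines were higher as a list. Of 25 tested, 12 rose, none fell and 13 were not called, and 15 rose adjusted over the list alone. Besides Sele, the adhesion molecules Vcam1 and Icam1 rose 3.64-fold (2.98 to 4.44) and 2.03-fold (1.67 to 2.47). Tnfaip3, a feedback inhibitor of NF-kappaB signalling, rose 2.22-fold (1.94 to 2.55). The median log2 change of the activation list was 0.73 (camera adjusted p = 7.0e-11, adjusted p = 0.485 with an estimated correlation). Of 19 genes of coagulation and fibrinolysis, 8 rose and 2 fell (11 and 2 adjusted over the list alone), with 9 not called. F2rl1, a receptor activated by proteases, rose 11.8-fold (7.72 to 18.1) from 14.1 ± 3.01 to 178 ± 38.9. Coagulation factor V (F5) rose 3.64-fold, the urokinase receptor Plaur 3.63-fold and thrombomodulin (Thbd), an anticoagulant receptor, 3.32-fold, so the risen members include genes on either side of clotting. Vwf, which supports platelet adhesion, fell from 10897 ± 604 to 7145 ± 428 (fold 0.66). Coagulation genes had a median of 0.60 (adjusted p = 1.1e-07, adjusted p = 0.485 with an estimated correlation), which was 0.91 without knock-out 3 or with the pericyte level in the fit and 1.03 with a minimum of 50.

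Genes downstream of KLF2, KLF4 and the kinase MEKK3, whose activity in endothelium is restrained by the CCM complex, were higher. Of 23 tested, 8 rose, none fell and 15 were not called, and 11 rose adjusted over the list alone. The secreted proteases Adamts1, Adamts9 and Adamts4, which cleave proteoglycans, rose 2.80-fold (2.23 to 3.52), 2.70-fold (1.98 to 3.67) and 2.34-fold (1.76 to 3.12), and Adamts1 reached 12575 ± 2344 normalised reads from 4440 ± 216. Klf4 rose 1.82-fold (1.46 to 2.27, adjusted p = 0.0101), and Klf2 had a fold of 1.55 (1.19 to 2.01) that was not called (adjusted p = 0.0676). Together the KLF targets had a median of 0.41 (adjusted p = 3.6e-09, adjusted p = 0.485 with an estimated correlation). Matrix proteases and their inhibitors, which share 5 genes with that list, had 6 of 26 members risen, none fallen and 20 not called (9 risen adjusted over the list alone). Besides the Adamts genes, the membrane-bound metalloprotease Adam15 rose 2.23-fold (1.86 to 2.68). The list's median was 0.07 and its adjusted p 0.00442, with adjusted p = 0.663 with an estimated correlation. Protease medians against the wild-type mean were 0.071, 0.016 and -0.019 in wild-type 1, 2 and 3. In knock-out 1, 2 and 3 they were 0.25, 0.33 and -0.13, so knock-out 3 lay below every wild-type library. Without wild-type 1 the adjusted p of Klf4 was 0.0502, and without knock-out 2 that of the protease list was 0.0861. The protease median moved by over 1.5 times in each of the 6 fits without 1 library, from 0.0078 without knock-out 2 to 0.24 without wild-type 1, and it was 0.38 with the pericyte level and 0.21 with the Y-linked level in the fit. Klf2 was called without knock-out 3 (0.0102), with the replicate block (0.0221), with array weights (0.0361) and with DESeq2 (0.00245).

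Genes of hypoxia and glycolysis were higher as a list. Of 28 tested, 15 rose, 1 fell and 12 were not called (21 and 1 adjusted over the list alone). Egln3, an oxygen-dependent prolyl hydroxylase that is itself induced by hypoxia-inducible factors, rose 11.1-fold (5.02 to 24.7). Ndrg1 rose from 192 ± 51.6 to 1348 ± 754, Ankrd37 rose 3.01-fold and the glycolytic enzyme Pfkp 1.88-fold (1.53 to 2.30). The glucose transporter Slc2a1, also a marker of the barrier, rose 1.88-fold, and Vegfa rose 2.72-fold (1.86 to 3.98). Hypoxia genes had a median of 0.78 (adjusted p = 2.7e-13, adjusted p = 0.485 with an estimated correlation). Its medians against the wild-type mean were 1.11, 0.84 and 0.41 in knock-out 1, 2 and 3. Among 29 genes of angiogenesis and tip cells, 10 rose and 4 fell, with 15 not called (13 and 6 adjusted over the list alone). The tip cell genes Apln and Kcne3 rose 2.33-fold (1.94 to 2.79) and 12.2-fold (7.41 to 20.2), whereas the chemokine receptor Cxcr4, also a tip cell gene, fell (fold 0.45, 0.38 to 0.54). For angiogenesis the median was 0.18 (adjusted p = 0.00442, adjusted p = 0.607 with an estimated correlation). The calls were lost for Vegfa without wild-type 1 or knock-out 2 (adjusted p = 0.0506 and 0.0511) and for the angiogenesis list without knock-out 2 (0.0965).

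Genes of capillary endothelium were lower as a list. All 15 had a lower mean log2 value in the knock-out, 9 of them fell, none rose and 6 were not called, and 14 fell adjusted over the list alone. Itm2a fell from 9395 ± 410 to 4554 ± 279 (fold 0.48, 0.42 to 0.56). The organic anion transporter Slc22a8, the lysolipid transporter Mfsd2a, which restrains transcytosis at the barrier, and the thyroxine transporter Slco1c1 had folds of 0.40 (0.32 to 0.51), 0.43 (0.34 to 0.53) and 0.50 (0.41 to 0.61). Capillary genes had a median of -0.82 (adjusted p = 2.8e-14, adjusted p = 0.485 with an estimated correlation). Of 33 genes of barrier transport and junctions, 8 of which are capillary genes, 9 fell, 2 rose and 22 were not called (12 fell and 5 rose adjusted over the list alone). The cationic amino acid transporter Slc7a1 fell from 29833 ± 1207 to 17106 ± 1081 (fold 0.57), while Slc2a1 was among the risen. Cldn5, the main tight junction claudin of brain endothelium, had a fold of 0.77 that was not called (adjusted p = 0.0813), but it was called with upper-quartile scaling (0.0458), quantile scaling (0.0347) and DESeq2 (0.0106). The barrier list had a median of -0.21 (adjusted p = 0.00442, adjusted p = 0.607 with an estimated correlation), but the groups overlapped. Barrier medians against the wild-type mean were -0.077, -0.050 and 0.11 in wild-type 1, 2 and 3. They were -0.0088, -0.27 and -0.25 in knock-out 1, 2 and 3. In Wnt/beta-catenin signalling, which maintains the barrier in brain endothelium, 7 of 27 genes fell, none rose and 20 were not called, and 16 fell adjusted over the list alone. The Wnt inhibitors and targets Apcdd1, Notum and Dkk2 had folds of 0.44 (0.36 to 0.54), 0.47 (0.39 to 0.57) and 0.31 (0.21 to 0.47). The Wnt list had a median of -0.35 (adjusted p = 1.3e-08, adjusted p = 0.485 with an estimated correlation). The barrier list lost its call without knock-out 3 (adjusted p = 0.0606), and its median was -0.08 without wild-type 3 and -0.12 without knock-out 2.

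Genes of arterial endothelium and of Notch signalling were lower. Of 20 arterial genes, 9 fell, 2 rose and 9 were not called (14 and 2 adjusted over the list alone). The Notch target Hey1 fell from 733 ± 83.0 to 249 ± 26.0 (fold 0.34, 0.28 to 0.42), and the gap junction gene Gja4 had a fold of 0.34 (0.23 to 0.50). The 2 arterial genes that rose were Vegfc (2.05-fold) and Tm4sf1 (1.55-fold). The arterial list had a median of -0.79 (adjusted p = 5.8e-07, adjusted p = 0.485 with an estimated correlation). Of 20 genes of Notch signalling, Hey1, Notch1 (fold 0.66) and its ligand Dll4 (0.65) fell, none rose and 17 were not called, with the same counts adjusted over the list alone. The Notch list had a median of -0.25 (adjusted p = 0.00151, adjusted p = 0.485 with an estimated correlation). Among 15 venous genes 3 rose, which were Sele, Vcam1 and Icam1, genes of the activation list as well, and 2 fell, of which Vwf is named above. The counts were the same adjusted over the list alone, 10 were not called, and the venous list had a median of 0.20 (adjusted p = 0.0462, adjusted p = 0.607 with an estimated correlation). Calls were lost for Vegfc without wild-type 1, wild-type 2 or knock-out 2 (adjusted p = 0.0613, 0.0737 and 0.0639), Tm4sf1 without wild-type 1 or 2 (0.0691 and 0.0829) and Notch1 without wild-type 2 (0.0673). They were also lost for Dll4 without wild-type 2, wild-type 3, knock-out 1 or knock-out 2 (0.107, 0.0681, 0.0505 and 0.0839) and the venous list without wild-type 3, knock-out 1 or knock-out 2 (0.116, 0.242 and 0.148), with a minimum of 50 (0.144), with quantile scaling (0.0532) and with array weights (0.0841). The venous median was 0.05 without wild-type 3, 0.09 with a minimum of 50 and 0.33 with the pericyte level in the fit. By library, the groups overlapped, as venous medians against the wild-type mean were 0.086 in wild-type 1 and 0.047 in knock-out 3.

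**Figure D2:**
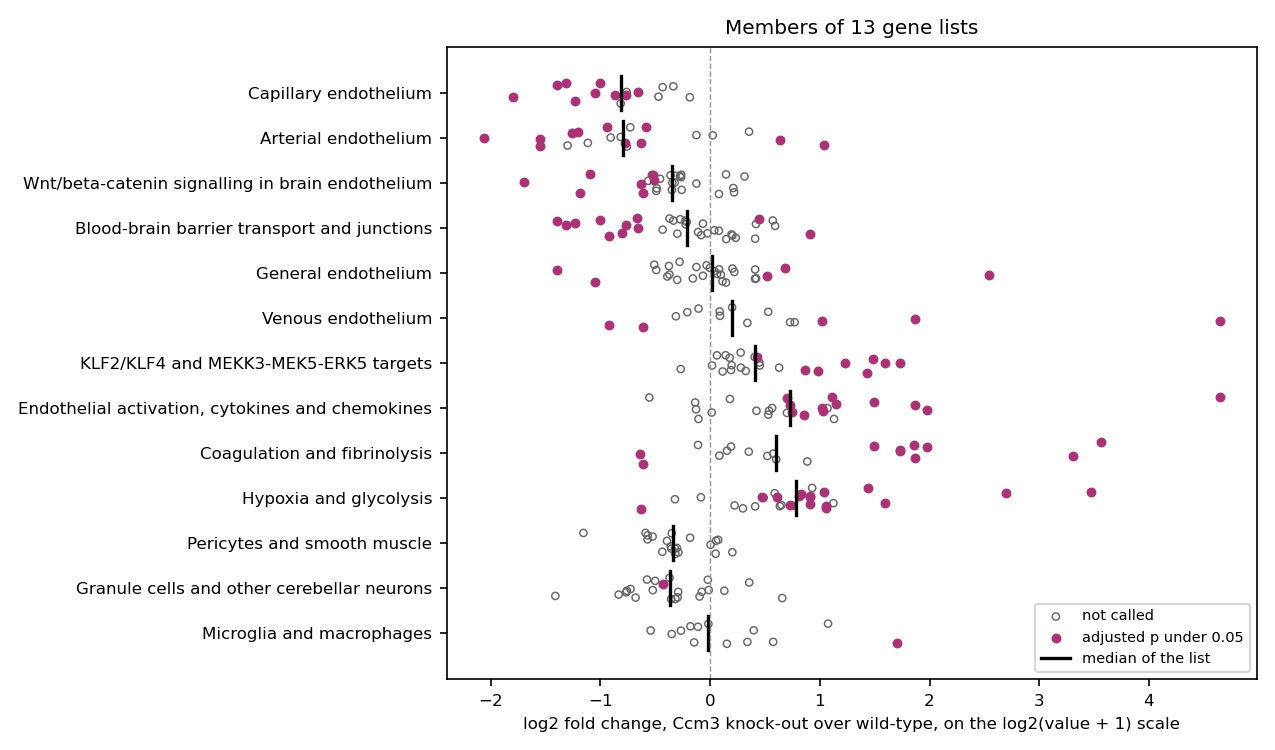
Log2 fold changes (horizontal axis, knock-out over wild-type on the log2(value + 1) scale) of the members of 13 gene lists; each point is a gene, filled points passed the test over all genes and black bars are list medians. All 15 capillary genes lie below 0 with a median of -0.82, and the medians of the hypoxia and activation lists are 0.78 and 0.73.

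Genes of general endothelium did not move as a list. Of 28 tested, 3 rose, 2 fell and 23 were not called (4 and 3 adjusted over the list alone), with a median of 0.02 (adjusted p = 0.688). Ly6a, a marker of large vessels, rose 5.84-fold (4.12 to 8.29), and Itm2a and Slco1a4 were the 2 that fell, Slco1a4 with a fold of 0.38. In TGF-beta and BMP signalling, 3 of 24 genes rose and 5 fell, with 16 not called (6 and 7 adjusted over the list alone), and the list was not called (median -0.06, mean 0.07, adjusted p = 0.517). Bmp2 rose from 52.0 ± 9.13 to 316 ± 26.0 (6.02-fold, 4.53 to 8.02), whereas Tgfb2 (fold 0.39, 0.33 to 0.47) and the decoy receptor Bambi (0.50, 0.43 to 0.58) fell. Of 18 genes of endothelial-to-mesenchymal transition, Ly6a and vimentin (Vim, 2.06-fold) rose and the cadherins Cdh11 (0.59) and Cdh2 (0.67) fell, with 14 not called (2 rose and 3 fell adjusted over the list alone, median -0.05, mean 0.01, list adjusted p = 0.591). Of 34 genes of extracellular matrix, 3 rose and 3 fell, with 28 not called (6 and 3 adjusted over the list alone, median -0.06, mean 0.0036, adjusted p = 0.904). Thrombospondin 1 (Thbs1) rose 3.93-fold (2.66 to 5.80), and biglycan (Bgn) and Col18a1 fell (folds 0.42 and 0.48). Calls were lost for Slco1a4 without knock-out 2 (adjusted p = 0.0571), Vim without wild-type 2 (0.0521), Cdh11 without wild-type 1, wild-type 2 or knock-out 2 (0.0707, 0.0628 and 0.0605) and Cdh2 without wild-type 1, 2 or 3 or knock-out 1 (0.0849, 0.0579, 0.0673 and 0.0518).

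Among 18 YAP/TAZ and Hippo genes Ccn2 rose 2.10-fold and Wwtr1 fell (fold 0.72), with 16 not called (4 and 1 adjusted over the list alone, list adjusted p = 0.0782). Wwtr1 was not called with the replicate block (adjusted p = 0.0669), with array weights (0.05) or in 5 of the 6 fits without 1 library (highest 0.144, without wild-type 3), all but the fit without knock-out 3. Ccn2 was not called without wild-type 1, 2 or 3 or knock-out 2 (0.0983, 0.117, 0.0512 and 0.0514). The YAP/TAZ list was called without knock-out 3 (0.018).

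Genes of the dissociation and immediate early response were called higher as a list, with 3 of 26 risen, none fallen and 23 not called (6 risen adjusted over the list alone). The groups overlapped, since the list medians against the wild-type mean were 0.01, 0.16 and -0.19 in wild-type 1, 2 and 3. They were 0.25, 0.35 and 0.12 in knock-out 1, 2 and 3. The small heat shock protein gene Hspb1 rose 3.19-fold (2.66 to 3.82), the stress-induced factor Atf3 2.27-fold (1.83 to 2.83) and Fosl2 1.77-fold. The list median was 0.21 (adjusted p = 0.000713, adjusted p = 0.607 with an estimated correlation), which was 0.32 without wild-type 2, 0.07 without wild-type 3 and 0.34 with the pericyte level in the fit. In the unfolded protein response Eif2ak3 (from 788 ± 19.1 to 1184 ± 124) and Trib3 (4.04-fold, from 7.96 ± 2.00 to 35.9 ± 12.1) rose, none fell and 21 of 23 were not called, with the same counts adjusted over the list alone (list adjusted p = 0.0898). Of 27 interferon response genes H2-D1 (1.48-fold) and Psmb8 (2.24-fold) rose, none fell and 25 were not called, with the same counts adjusted over the list alone (list adjusted p = 0.23). Of 26 genes of autophagy and lysosome, Gabarapl1 fell (fold 0.64), none rose and 25 were not called (1 rose and 1 fell adjusted over the list alone, list adjusted p = 0.29). None of 36 proliferation genes changed over all genes or adjusted over the list alone, with a list adjusted p of 0.248. Mcm6 had a fold of 0.61 (adjusted p = 0.0693). Of the 6 fits without 1 library, 5 ended the calls of H2-D1 and Psmb8, all but the fit without knock-out 3 (highest adjusted p = 0.12 without wild-type 2 and 0.139 without knock-out 2). Calls ended without wild-type 1, 2 or 3 or knock-out 2 for Eif2ak3 (0.0646, 0.0962, 0.0625 and 0.063) and Gabarapl1 (0.131, 0.161, 0.103 and 0.0856), without wild-type 1 or 2 or knock-out 2 for Fosl2 (0.0849, 0.0883 and 0.0605) and without wild-type 1 or 2 for Trib3 (0.0739 and 0.0862), which was kept in the filter in 3 of these fits. Psmb8 was not called with quantile scaling (0.0541). Calls were gained by Mcm6 without knock-out 1 (0.0388), with array weights (0.0284) and with DESeq2 (0.00823), by the unfolded protein list without wild-type 1 (0.034) or knock-out 3 (0.0192) or with the Y-linked level (0.0363) or the pericyte level (0.00612) in the fit, and by the proliferation list without wild-type 3 (0.0254) or knock-out 2 (0.00745).

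Cytoplasmic ribosomal protein genes were slightly lower, 42 of 46 having a lower mean log2 value in the knock-out. Rpl22 rose 2.02-fold (1.70 to 2.41), Rpl14 fell (fold 0.76) and 44 were not called, with the same counts adjusted over the list alone. The list median was -0.21 (adjusted p = 2.5e-05, adjusted p = 0.607 with an estimated correlation), which was -0.13 without wild-type 1 and -0.14 and -0.12 with the Y-linked and pericyte levels in the fit. Ribosomal protein genes have many processed pseudogenes that can share their reads. Rpl14 was not called with the replicate block (adjusted p = 0.0808) or without wild-type 1, 2 or 3 or knock-out 1 or 2 (0.158, 0.134, 0.0865, 0.0627 and 0.098). None of 11 mitochondrially encoded genes changed over all genes, and none rose and 2 fell adjusted over the list alone. The list median was -0.60 (adjusted p = 0.00257, adjusted p = 0.607 with an estimated correlation), and mt-Nd2 had a fold of 0.51 (adjusted p = 0.0511, but 0.0246 without knock-out 1, 0.0463 with a minimum of 50, 0.0446 with upper-quartile scaling, 0.0161 with array weights and 0.000481 with DESeq2). The groups overlapped, since the mitochondrial list medians against the wild-type mean were -0.36, 0.19 and 0.15 in wild-type 1, 2 and 3. They were -0.02, -0.84 and -1.01 in knock-out 1, 2 and 3. Mitochondrial ribosomal RNA took 13.2%, 17.5% and 19.0% of the reads in wild-type 1, 2 and 3 and 16.6%, 9.92% and 10.5% in knock-out 1, 2 and 3.

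Erythroid markers in the isolates were lower in the knock-out, whereas the platelet gene Tubb1 rose. The fibroblast and pericyte lists were called lower with the preset correlation, but the groups overlapped. Fibroblast medians against the wild-type mean were 0.22, 0.16 and -0.54 in wild-type 1, 2 and 3 and -0.15, -0.35 and -0.80 in knock-out 1, 2 and 3. Pericyte medians were 0.36, 0.21 and -0.53, and -0.30, -0.16 and -0.58. As small a camera p came in 3 (fibroblast) and 4 (pericyte) of the 10 splits into 3 and 3, the genotype split included. Among 12 platelet and erythroid genes 1 rose and 5 fell, with 6 not called (2 and 6 adjusted over the list alone). The haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs, near-identical copies of which share reads, had folds of 0.44, 0.40 and 0.42, and the erythrocyte enzyme gene Bpgm had a fold of 0.51 (0.42 to 0.64). The gene that rose was Tubb1, a tubulin of platelets (7.91-fold, 2.80 to 22.4, adjusted p = 0.0351), with 26.4, 153 and 159 normalised reads in knock-out 1, 2 and 3 and a wild-type mean of 10.3 ± 2.58. The platelet integrin gene Itga2b had a fold of 1.77 (adjusted p = 0.196) and rose adjusted over the list alone, and Gp1bb, the third platelet gene tested, had a fold of 1.08. Platelets carry CD31, and the coagulation list, some of whose genes platelets express, had medians against the wild-type mean of 1.13, 0.70 and 0.48 in knock-out 1, 2 and 3. The list of platelet and erythroid genes had a median of -0.81 (adjusted p = 0.00249, adjusted p = 0.607 with an estimated correlation), which was -0.53 without wild-type 1. Of 17 fibroblast and meningeal genes 3 fell, none rose and 14 were not called (5 fell adjusted over the list alone), among them Apod (fold 0.61, 0.54 to 0.69) and Lama1 (0.55). The fibroblast list had a median of -0.39 (adjusted p = 0.00249, adjusted p = 0.607 with an estimated correlation). None of 20 pericyte and smooth muscle genes changed over all genes or adjusted over the list alone, with a list median of -0.34 (adjusted p = 0.0057, adjusted p = 0.663 with an estimated correlation), and Mylk, a contractile kinase gene, had a fold of 0.66 (adjusted p = 0.162, but 0.0279 without wild-type 3 and 0.0302 with DESeq2). The call of Tubb1 was lost without wild-type 1, 2 or 3 or knock-out 2 or 3 (adjusted p = 0.0924, 0.14, 0.088, 0.123 and 0.08), and Itga2b was called without knock-out 1 (0.0229). Calls were lost without wild-type 2 or knock-out 2 for Hba-a1, Hba-a2 and Hbb-bs (highest adjusted p = 0.0854) and without wild-type 2 for Lama1 (0.0523). They were also lost without knock-out 3 (0.0981) or with the pericyte level in the fit (0.0985) for the fibroblast list, and without wild-type 1, wild-type 2 or knock-out 3 (0.109, 0.0751 and 0.0541) or with the pericyte level in the fit (0.908) for the pericyte list. The last of these is no test of the pericyte list, since the pericyte level is the mean of the list's own genes. The fibroblast median was -0.72, -0.60 and -0.22 without wild-type 3, knock-out 1 and knock-out 3, -0.64 with array weights and -0.12 with the pericyte level. The pericyte median was -0.16 and -0.61 without wild-type 1 and 3 and -0.21 with the Y-linked level.

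Of 22 astrocyte and Bergmann glia genes 1 fell, none rose and 21 were not called, with the same counts adjusted over the list alone. That gene was Gja1 (fold 0.57, 0.49 to 0.66), which encodes connexin 43, a protein of vascular cells as well, and Aqp4 had a fold of 0.40 that was not called (adjusted p = 0.131, but 0.00196 with the replicate block and 0.0402 with array weights). The astrocyte list had a median of -0.33 (adjusted p = 0.0284, adjusted p = 0.663 with an estimated correlation). The groups overlapped, with astrocyte medians against the wild-type mean of 0.18, 0.16 and -0.44 in wild-type 1, 2 and 3. They were -0.22, -0.24 and -0.47 in knock-out 1, 2 and 3. Of 22 genes of granule cells and other neurons, Zic2 fell (fold 0.74), none rose and 21 were not called, with the same counts adjusted over the list alone, a median of -0.36 and adjusted p = 0.0199 (adjusted p = 0.663 with an estimated correlation). Zic2 was not called with the replicate block (adjusted p = 0.0757) or without wild-type 1, 2 or 3 or knock-out 1 or 2 (0.0719, 0.171, 0.116, 0.0536 and 0.0911). The list medians of the neuronal genes against the wild-type mean were -1.03, -0.71 and 0.61 in knock-out 1, 2 and 3. None of 20 oligodendrocyte genes changed over all genes or adjusted over the list alone (median -0.35, list adjusted p = 0.163, but 0.00527 with the replicate block, 0.00187, 0.04 and 0.00347 without wild-type 1, wild-type 2 and knock-out 3, and 0.00526 and 4.5e-09 with the Y-linked and pericyte levels in the fit). Of 9 genes of Purkinje cells and interneurons, Kit fell (fold 0.76, adjusted p = 0.0929 with the replicate block, and not called in 5 of the 6 fits without 1 library, all but that without knock-out 3, with 0.187 without wild-type 2 as the highest), none rose and 8 were not called, with 2 fallen adjusted over the list alone (list adjusted p = 0.243, and 0.0344 without wild-type 3). Of 13 microglial genes Lyve1 rose from 9.28 ± 4.72 to 30.6 ± 5.07, none fell and 12 were not called, with the same counts adjusted over the list alone (median -0.02, mean 0.20, list adjusted p = 0.554). Lyve1 was called in none of the 6 fits without 1 library (adjusted p from 0.0541 without wild-type 2 to 0.151 without wild-type 1), nor with the replicate block (0.0722), array weights (0.154) or edgeR (0.056). None of 12 ependymal and choroid plexus genes changed, over all genes or adjusted over the list alone (median 0.27, list adjusted p = 0.715). Their medians against the wild-type mean were 0.62, -0.28 and -0.35 in wild-type 1, 2 and 3 and 1.74, -0.27 and -0.65 in knock-out 1, 2 and 3, and the list median was -0.47 without knock-out 1. Calls were lost for the astrocyte list without wild-type 1, wild-type 2 or knock-out 3 (adjusted p = 0.14, 0.0878 and 0.163), with quantile scaling (0.0626), and with the Y-linked (0.0767) or pericyte level (0.582) in the fit. The astrocyte median was -0.18, -0.53 and -0.18 without wild-type 1, wild-type 3 and knock-out 3, and 0.02 with the pericyte level. Calls of the neuronal list were lost without wild-type 2, knock-out 1 or knock-out 2 (0.0503, 0.398 and 0.192), with a minimum of 50 (0.0549) and with DESeq2 (0.0909), and the neuronal median was -0.20 without knock-out 1, -0.97 without knock-out 3, -0.23 with edgeR and -0.22 with DESeq2.

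The first principal component of the 2000 most variable genes held 39.8% of the variance and set all 3 wild-type libraries (-14.5, -22.2 and -19.9) below all 3 knock-out libraries (44.1, 13.9 and -1.38). Knock-out 3 lay nearest to the wild-type libraries on it and apart from the other libraries on the second component (29.1%), at -38.3. Of the 5 sex-linked genes none changed, over all genes or adjusted over the list alone (list adjusted p = 0.266). The Y-linked gene Ddx3y had 0, 1938 and 921 normalised reads in wild-type 1, 2 and 3 and 2106, 473 and 948 in knock-out 1, 2 and 3. Xist, transcribed from the inactive X chromosome, had 16018, 5.34 and 10856 in wild-type 1, 2 and 3 and 41.5, 9398 and 7802 in knock-out 1, 2 and 3.

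**Figure D3:**
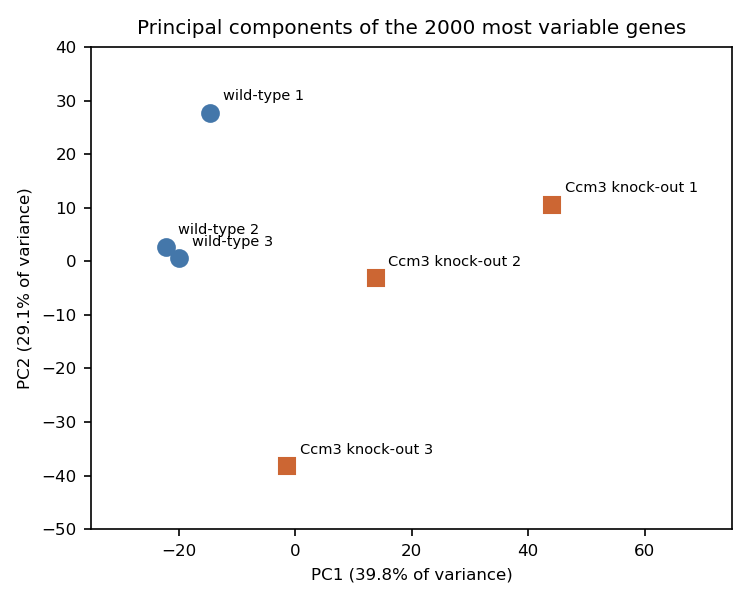
First and second principal component scores (axes, with their share of the variance) of the 2000 most variable genes, on log2(value + 1). Circles are wild-type and squares Ccm3 knock-out libraries; the wild-type scores on the first component run from -22.2 to -14.5 and those of the knock-out from -1.38 to 44.1.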

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

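The covariate fits with the Y-linked and pericyte levels were chosen after seeing the data. The number of changed genes lay between 769 and 1217 under the other pseudocounts, filters and scalings, robust or array-weighted limma, the replicate block and edgeR. Under DESeq2 it was 1373 (805 rose, 568 fell), with the Y-linked level in the fit 457 (271 rose, 186 fell), with the pericyte level 637 (376 rose, 261 fell), and with a minimum of 2-fold 359. Without 1 library it ran from 283 to 1021 (185 to 637 rose, 98 to 384 fell). It was 399, 283, 439 and 459 without wild-type 1, 2 and 3 and knock-out 2. The log2 change of Pdcd10 ran from -1.61 to -1.11 without 1 library. Smaller groups and fewer residual degrees of freedom come with leaving out a library. The covariate fits and the replicate block also leave fewer residual degrees of freedom, and the causes of the shifts beyond this were not tested. The block by replicate number gave 769 changed genes, 686 of them shared with the 879, and 22 lists. It left the calls of Rpl14, Robo4, Zic2, Lyve1, Kit and Wwtr1 behind, added Klf2, Aqp4, Sqstm1, Ier3, Tubb3 and the oligodendrocyte list, and changed no other call of a gene or list named in the text. Of 113 named genes that changed, 70 were called in every fit without 1 library, and the test of no called gene or list turned its direction in any alternative. The median of the called astrocyte list turned from -0.33 to 0.02 with the pericyte level, where its call was lost, and that of the pericyte list went to -0.0017. For the pericyte list this fit is no test, since the changes of its genes average 0 there by construction. The Y-linked level ended the calls of 24 of the 113 genes, among them Kank4, Tm4sf1, Vegfc, Gabarapl1, Rpl14, Fosl2, Cdh2, Fbln1, Robo4, Zic2, H2-D1, Psmb8, Lyve1, Kit, Eif2ak3, Trib3, Ccn2, Wwtr1, Klf9, Anxa5 and Tubb1, and of the astrocyte list, and added mt-Nd2 and the oligodendrocyte and unfolded protein lists. The pericyte level ended those of 20 genes, among them Cdh11 and all of the former except Psmb8, Eif2ak3, Wwtr1 and Anxa5, and of the astrocyte, fibroblast and pericyte lists. It added Klf2, Ier3, Tubb3, Gpr17 and the oligodendrocyte and unfolded protein lists. Lists called numbered 17 to 22 in all alternatives except the estimated correlation (0; 2 lists with unadjusted p under 0.05) and fry (4), and 12 of 21 were called in every fit without 1 library. PC1 held 42.7% of the variance with 500 genes and 38.1% with all genes. Directions that turned were all of results without a call, and their causes were not tested. In log2 units they were the microglial list with a minimum of 50 (-0.0809), the matrix list with array weights (-0.121), the block (-0.0615), edgeR (-0.0218) and DESeq2 (-0.0157), the general endothelial list with array weights (0.0524), and the sex-linked list with DESeq2 (0.308). With the Y-linked level they were proliferation (0.0407), Kdm5d (-0.0484) and Eif2s3y (-0.124), with the pericyte level the mesenchymal transition list (0.168), proliferation (0.0286) and Car8 (0.0320), and with fry the mesenchymal transition list (-0.0493). Kdm5d and Eif2s3y are among the genes that make up the Y-linked level. The changes of those genes average 0 in that fit by construction, so turns among them carry no information. Without 1 library, directions turned for the following results (lowest to highest): proliferation -0.179 to 0.0605, sex-linked genes -0.44 to 3.66, ependyma -0.47 to 0.63, matrix -0.144 to 0.0766, general endothelium -0.0462 to 0.0956, the oligodendrocyte lineage -0.86 to 0.14, interferon 0.0139 to 0.168, autophagy -0.116 to -0.00547, mesenchymal transition -0.26 to 0.11 and TGF-beta -0.127 to 0.0268. For single genes these ranges were Kl -0.22 to 1.05, Car8 -1.40 to 0.0499, Ddx3y -0.44 to 5.02, Uty -0.41 to 3.66, Kdm5d -0.52 to 4.11 and Eif2s3y -0.52 to 3.51. Direction here is that of the test, so a median can keep its sign. The depth of 11075769 to 21142333 reads limits what can be said of genes with few reads. The filter removed only some of these, and Trib3, Lyve1 and Tubb1, which were called, had few reads in the wild-type libraries.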

Other observations

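The tests of gene families, of the endothelial share, of depth, of residual Pdcd10 and of both readings of the sex-linked transcripts were chosen only after the results were seen. Among 218 families of at least 8 genes that share a symbol stem, the Krüppel-like factors and the annexins were called higher in the knock-out, and the stems Rpl (adjusted p = 0.00346), Rps, Tspan and Tbx (0.0439 each) were called lower. With an estimated correlation no family was called (adjusted p = 0.989 for each of these 6). Of 13 Klf genes 4 rose and none fell (camera adjusted p = 0.000167). Besides Klf4, these were Klf6 (1.98-fold, 1.52 to 2.58), Klf9 (1.78-fold) and Klf10 (1.68-fold, 1.44 to 1.96), transcription factors of which Klf10 is a TGF-beta target. Of 8 annexin genes 5 rose and none fell (adjusted p = 0.00102). Anxa1, an anti-inflammatory mediator, rose from 130 ± 5.89 to 633 ± 170 (4.73-fold, 3.44 to 6.50), and Anxa2, which binds plasminogen together with S100a10, rose 2.81-fold (2.20 to 3.60). Anxa3, Anxa5 and Anxa7 rose 1.49-fold, 1.48-fold and 1.65-fold. S100a6, a calcium-binding relative of S100a10, rose 9.87-fold (4.92 to 19.8). Calls were lost for Klf6 and Anxa3 without wild-type 1 or 2 (adjusted p = 0.0575 and 0.0702, 0.0621 and 0.0669), for Anxa7 without wild-type 2 (0.0536), for Klf9 in 4 and for Anxa5 in 5 of the 6 fits without 1 library (highest adjusted p = 0.0887 and 0.128), and for Klf4 without wild-type 1 (0.0502).

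Of 236 solute carrier genes with the stem Slc, 24 fell and 9 rose, and the family was not called (adjusted p = 0.435). The zinc and manganese transporter Slc39a8 fell from 8356 ± 423 to 3403 ± 302 (fold 0.41, 0.35 to 0.48), and Slc16a9 had a fold of 0.37 (0.30 to 0.46). Slc16a3, the lactate exporter of glycolytic cells, rose from 15.7 ± 7.41 to 231 ± 89.2 (14.3-fold, 7.04 to 29.0).

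The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The genotype split gave 879 changed genes and the highest other split 0, so 1 of 10 splits gave as many. For lists, 3 of 10 splits called at least as many as the genotype split, which called 21, and the highest other split called 24. For 6 lists, the capillary, coagulation, activation, hypoxia, KLF and Wnt lists, the genotype split had the smallest p of all 10. As small a p, the genotype split included, came in 2 splits for the angiogenesis, arterial, Notch, dissociation, and platelet and erythroid lists. It came in 3 splits for the barrier, mitochondrial, venous and fibroblast lists and in 4 for the astrocyte, ribosomal, protease and pericyte lists. For the neuronal list it came in 6. Of the splits that part all 3 pairs of equal number, the others also gave 0 genes.

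The capillary genes were lower in the knock-out (median -0.82). A lower share of endothelial cells in the knock-out isolates is argued against. The 21 general endothelial genes outside the capillary, arterial, venous and barrier lists had a median of 0.0642 (95% interval -0.278 to 0.220), and the interval lies above -0.408, which is 0.5 of the capillary median. This interval treats the genes as independent and describes the spread between genes, not between isolates. By library, the whole general endothelial list had medians against the wild-type mean of -0.0123, 0.0644 and -0.191 in knock-out 1, 2 and 3. Those of the capillary list were -1.08, -0.868 and -0.634. With the Y-linked level in the fit the capillary median was -0.917, with 15 of 15 genes lower (camera adjusted p = 4.58e-16). This fit cannot decide on a different mix of sexes, since the level is on a log2 scale and mostly sets wild-type 1 apart. Y-linked genes were at 0.0664% of the male libraries in wild-type 1 and at 20.5% to 109% in the other libraries. A change in the state of capillary cells and a smaller share of capillary cells among endothelial cells both stay open, and the design does not separate them.

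In the size of change on called genes, knock-out 3 differed less from the wild-type libraries than the others did. Over all genes it was not the closest to wild-type 1 and 2. Pearson correlations with wild-type 1, 2 and 3 were 0.972, 0.975 and 0.965 for knock-out 2 and 0.956, 0.970 and 0.969 for knock-out 3. On the 1021 genes called without knock-out 3, its median log2 change in the direction of the others was 0.616, which is 67.8% of their 0.908. On the genes called without knock-out 1 (669) or knock-out 2 (459), the library left out reached 114% (0.998 against 0.876) and 95.7% (0.965 against 1.01) of the others. Its lower depth is argued against, since knock-out 1 and 2, thinned to its reads and each measured on the genes called without it, stayed at 93.6% or more in 20 thinnings. More cells that kept Pdcd10 may account for it, as Pdcd10 was at 53.2% of the wild-type mean there, but knock-out 1 kept more than knock-out 2 (39.7% and 26.6%) and yet changed more, and 3 libraries are too few to decide.

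In wild-type 3, knock-out 2 and knock-out 3, Xist and Y-linked genes were both abundant, and the sample titles do not say how many mice a library holds. RNA of females and males in 1 library is a candidate explanation. Xist as a percent of its highest library and the 4 Y-linked genes as a percent of the male libraries added to between 79.2 and 118 in these libraries, and the Y-linked genes of a library spanned at most 12.8 percentage points. Reads passed between libraries at sequencing are argued against, since libraries of 1 sex held at most 0.259% of the other sex's level. An isolate pooled from littermates and a mixture made later stay open, as no label bears on them.

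Genes near Pdcd10 were tested for alleles of another strain that could have stayed linked to the targeted locus. Within 20 Mb of Pdcd10, 18 of 230 genes changed (7.83%, exact 95% interval 4.70 to 12.1), against 6.22% elsewhere (Fisher's exact p = 0.334, two-sided). The interval leaves the question undecided. S100a10, S100a6, Adam15, Tm4sf1 and Wwtr1, named above, are among the 18 changed genes in this window, so the question applies to them as well.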
